A study of Mus musculus with 14 samples.

How the data were processed

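RNA from the livers of male C57Bl/6J mice was measured on Illumina MouseRef-8 v2 beadchips, 1 array per mouse. Mice had been fed a diet with sucrose (7 arrays) or an isocaloric diet with palatinose (7 arrays). Per the labels, total RNA was purified with RNeasy columns and DNase, then amplified and labelled with biotin by the Illumina TotalPrep kit. The deposited non-normalized table holds a signal intensity for each probe and array, on a linear scale and rounded to whole numbers. It also holds a detection p-value for each probe and array, per the file headers. Between 23.1% and 26.4% of the intensities of an array lie below 0, so background had been subtracted before the table was written. The table written by the authors for the series holds intensities on a linear scale that were normalized between arrays. Its 14 column medians are all 21 and its values run from 2 to 23062; its method of normalization is not given in the sources used here.

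The array platform has 25697 probes, of which 23978 carry 1 gene symbol and 1719 are unnamed here. Each of the 14 columns of the authors' table was matched to the non-normalized column with which its rank correlation was highest. Each match was to a different column, at 0.99987 or above against at most 0.920 for any other column, and all 14 matches joined columns of the same diet. Arrays are named here by diet and the code of their column in the non-normalized table, such as sucrose array SUC_424_02.

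The non-normalized intensities were corrected for background, normalized and put on the log2 scale with neqc of limma 3.58.1 under R 4.3.3. The background was estimated from the detection p-values, an offset of 16 was added, and arrays were quantile normalized. A probe was kept if its detection p-value was under 0.05 on at least 7 of the 14 arrays, which left 11628 probes. For a gene with several kept probes, the probe with the highest mean over all 14 arrays was tested. The 683 kept probes that are unnamed here were tested by themselves. This gave 8829 features, of which 8146 are named genes. Each array measured 11457 to 12476 probes at a detection p-value under 0.05. On arrays there are no counts, and the number of arrays limits the precision.

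The diets were compared with lmFit and eBayes of limma, 7 arrays against 7, two-sided, with no covariate. Differences are log2 values of palatinose minus sucrose, so that a positive value is higher with palatinose. Intervals are 95% confidence intervals from the same model. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05.

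The following choices were made before the data were examined: the groups, the test, the filter, 41 gene lists, a panel of 20 metabolic genes, most alternatives, and a rule for the genes to be named. The rule takes the 10 genes with the largest difference in each direction among those that pass. Where fewer than 5 pass in a direction, it adds those with the smallest p until there are 5. It also takes the panel, and up to 4 members, smallest p first, of a described list. Which 13 lists are described with named members was chosen after values had been seen. Of the lists, 25 are pathways, 2 follow sample handling and 14 are markers of cell types or tissues. The 33 lists with at least 5 measured members were tested with camera of limma at its preset correlation between genes of 0.01. The alternatives to it were camera with an estimated correlation, fry, and an exact permutation test of the mean of the list per mouse over the 3432 labelled splits of the arrays. The intervals of list means treat each mouse as 1 value. Adjusted p-values of lists were computed over the 33 lists.

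For tissue markers, a gene counted as detected on an array at a detection p-value under 0.01 for any of its probes. Correlations across the 14 arrays have permutation p-values from 100000 resamples, and exact ones within a diet. The other settings were no background correction, cyclic loess or median scaling in place of quantile normalization, the authors' values, no filter and a stricter filter. They also covered trend and robust settings of eBayes, array weights, all or averaged probes of a gene, a block for the replicate number, and leaving out each array in turn. Alternatives added after the data were seen were the block on the authors' values, the column code as a random block (statmod 1.5.0), and 3 sets of left-out arrays. The slide of each array is not given in the sources used here, so no slide block was run.

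The comparison was tested on simulated data: 10 sets with the size and spread of these arrays and 200 changed genes each. At a log2 difference of 0.32, 39.3% of changed genes were called, at 1.5-fold 86.0%, and at 2-fold 97.4%. Of 100 calls 4.88 were false, and 0 of the 10 sets with nothing changed had a call. Each gene was drawn independently, so these sets held no correlation between genes, no array that deviates as a whole and no other tissue. With nothing changed they averaged 457.3 genes at an unadjusted p under 0.05, whereas another split of the real arrays reached 1078. The changes were added to log2 values that already held the offset of 16. A real fold change of a dim gene would appear smaller there than the simulated one. The rates hold for that simpler setting and need not hold for these arrays.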

Results

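The data describe gene expression in the livers of 14 male mice fed isocaloric diets that differed in their disaccharide. Sucrose and palatinose (isomaltulose) are isomers: both join a glucose to a fructose, by different glycosidic bonds, and palatinose is digested more slowly. The titles give 22 weeks on the diet, whereas the age label reads 18 weeks. Both cannot hold if that age is the age at which the liver was taken. The title of the series places the comparison in a study of diet, fatty liver, insulin resistance and the incretin hormone GIP. Each diet has 7 arrays. Mean signal per array was 190 to 257, and 44.6% to 48.6% of the probes were detected. Pearson correlations between arrays were 0.972 to 0.994, and no pair of arrays held identical values. The Y-linked Eif2s3y was detected on 14 arrays and Xist, expressed from the inactive X chromosome of females, on 0.

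No liver gene passed the test between the mice on palatinose and those on sucrose. With limma, 0 of 8829 features had an adjusted p under 0.05, the smallest adjusted p was 0.316, and 627 features had an unadjusted p under 0.05 (331 higher and 296 lower with palatinose) where chance alone gives 441.4. For 8413 features (95.3%) the 95% interval lay within 1.5-fold in either direction, and for 8763 (99.3%) within 2-fold. Each interval holds for 1 feature by itself, so together they are no joint bound on what was missed. The offset of 16 draws log2 differences of dim probes toward 0. For such probes the intervals do not bound the fold change of the RNA itself. Of 16593 named genes on the array 8146 were tested. The estimates of 18 features were over 1.5-fold and those of 2, Socs2 and Hsd3b5, over 2-fold. Without 1 array these came down to -0.88 log2 for Socs2 (SUC_421_03 left out) and -0.62 for Hsd3b5 (PAL_430_01 left out). Without the filter on dim probes 1 gene, Atg2a, passed, at +0.30 log2 and an adjusted p of 0.0317 (0.0317 to 0.902 over its alternatives).

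The 10 genes with the smallest p, 5 in each direction, did not pass the adjusted threshold. Osbpl11, of the oxysterol-binding protein family, had a log2 intensity of 5.90 ± 0.13 (SD, n = 7) with sucrose and 6.29 ± 0.09 with palatinose, a difference of +0.39 (95% interval 0.24 to 0.54, adjusted p = 0.316). Atg2a, which transfers lipid to forming autophagosomes, had 7.11 ± 0.05 and 7.41 ± 0.08, a difference of +0.30 (0.18 to 0.42, adjusted p = 0.319), and its other kept probe gave +0.14. Ncoa4, the receptor that delivers ferritin to autophagy, had 7.27 ± 0.18 with sucrose and 6.80 ± 0.17 with palatinose, a difference of -0.47 (-0.67 to -0.28, adjusted p = 0.324). The other genes with higher values were Cluh, which binds mRNAs of mitochondrial proteins (+0.38), Ddit3, the stress transcription factor CHOP (+0.40), and Mta2, of the NuRD chromatin complex (+0.29). Lower values were measured for Adss, of purine synthesis (-0.37), Zfp809, which silences retroviral DNA (-0.51), the nuclease gene Dnase2b (-0.34) and Sec23a, of the COPII coat of secretory vesicles (-0.48). The 2 other kept probes of Dnase2b gave -0.00 and 0.02. For each of these 10 genes, all 7 palatinose arrays lay on the same side of the sucrose mean. The genes were chosen by their p on the same arrays, so this is no separate support.

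No transcript of fat synthesis passed the test between the diets. Of the 18 measured members of the de novo lipogenesis list, 9 were higher and 9 lower with palatinose and 0 passed, either over all genes or adjusted over the list alone. The mean difference of the list was 0.01 log2 (95% interval -0.10 to 0.12, camera adjusted p = 0.928); the list mean and median were above 0 and the direction of the camera test was down. Srebf1, a transcription factor that drives lipogenesis, differed by +0.04 (-0.20 to 0.29), the desaturase gene Scd1 by -0.06 (-0.26 to 0.15), and Acaca, for acetyl-CoA carboxylase, by +0.18 (-0.03 to 0.40; +0.11 without PAL_430_01). Mlxipl, the carbohydrate sensor ChREBP, differed by +0.05 (-0.23 to 0.32) and Pklr, for liver pyruvate kinase, by -0.13 (-0.52 to 0.26), with +0.04 on its other probe. Thrsp, named after its values were seen, varied more between mice and gave +0.11 (-0.77 to 0.98). Gpam gave -0.22, Fads2 +0.18 and Acss2 -0.13 (-0.07 without SUC_411_03). Fasn, for fatty acid synthase, was detected on only 7 arrays by its 1 probe and gave +0.09 (-0.09 to 0.26, and +0.04 without PAL_418_07). Its signal of 6 to 15 lay below the offset of 16, which draws such a difference toward 0. The sign of Srebf1, Scd1, Mlxipl and Pklr turned under at least 1 alternative.

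No gene of fructose or glucose handling passed either. Of 8 measured fructose genes 5 were higher and 3 lower and 0 passed over all genes or adjusted over the list alone (mean 0.03, -0.12 to 0.18, camera adjusted p = 0.818). Khk, the ketohexokinase that commits fructose to metabolism, differed by +0.01 (-0.28 to 0.31), and by -0.10 on its other probe. Its sign turned under 12 of 27 alternatives, cyclic loess and median scaling among them. Glyctk gave +0.23, the transporters Slc2a8 +0.20 and Slc2a2 -0.22, and Txnip +0.09; without SUC_424_02 Glyctk gave +0.13, Slc2a8 +0.12 and Txnip -0.07. The other kept probes of Glyctk lay between -0.25 and 0.13. Of 13 genes of gluconeogenesis and fasting 7 were higher and 6 lower and 0 passed (mean -0.02, -0.20 to 0.16, camera adjusted p = 0.894), with a median above 0. Pck1, for the gluconeogenic enzyme PEPCK, gave -0.34 (-0.73 to 0.05; -0.21 without SUC_424_02) and G6pc +0.06 (-0.38 to 0.49). Lpin1 gave -0.37 (-0.10 without SUC_411_03), Pcx +0.16 and Ppargc1a -0.10 (-0.04 without PAL_417_02). Fgf21, a hormone made by liver under sugar or fasting, gave +0.20 (-0.45 to 0.86), with +0.06 without PAL_407_04 and +0.37 without SUC_421_03. The mean differences of the glycolysis list (0.02) and the glycogen list (-0.04) had camera adjusted p-values of 0.902 and 0.574.

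No lipid droplet gene passed between the diets, and some, such as Cidea, varied widely within each diet. Of the 20 measured members of the steatosis list 15 were higher and 5 lower with palatinose, and 0 passed (mean 0.12, -0.08 to 0.31, camera adjusted p = 0.354). Cidea, for a droplet protein that is raised in fatty liver, had 8.99 ± 1.77 (SD, n = 7) with sucrose and 9.65 ± 1.11 with palatinose, a difference of +0.66 (-0.76 to 2.08) that was +0.15 without SUC_408_02 and +1.00 without SUC_411_03. Cidec gave +0.43 (-0.34 to 1.19; +0.28 without SUC_415_02 and +0.66 without PAL_407_04), Plin4 +0.33 (+0.50 without SUC_411_03), Plin5 +0.21 (-0.05 on its other probe), Plin3 +0.13 (+0.08 without SUC_424_02), and Mogat1 +0.04 (-0.47 to 0.56). Plin2, the droplet coat of hepatocytes, differed by -0.01 (-0.16 to 0.15) and Pparg by -0.00 (-0.24 to 0.24). Plin2, Pparg, Mogat1 and Plin3 turned sign under at least 1 alternative. The intervals of Cidea and Cidec leave differences over 2-fold open. Cpt1a and Cd36 were detected on 0 arrays by their probes, and Gipr has no probe that is named here.

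**Figure D1:**
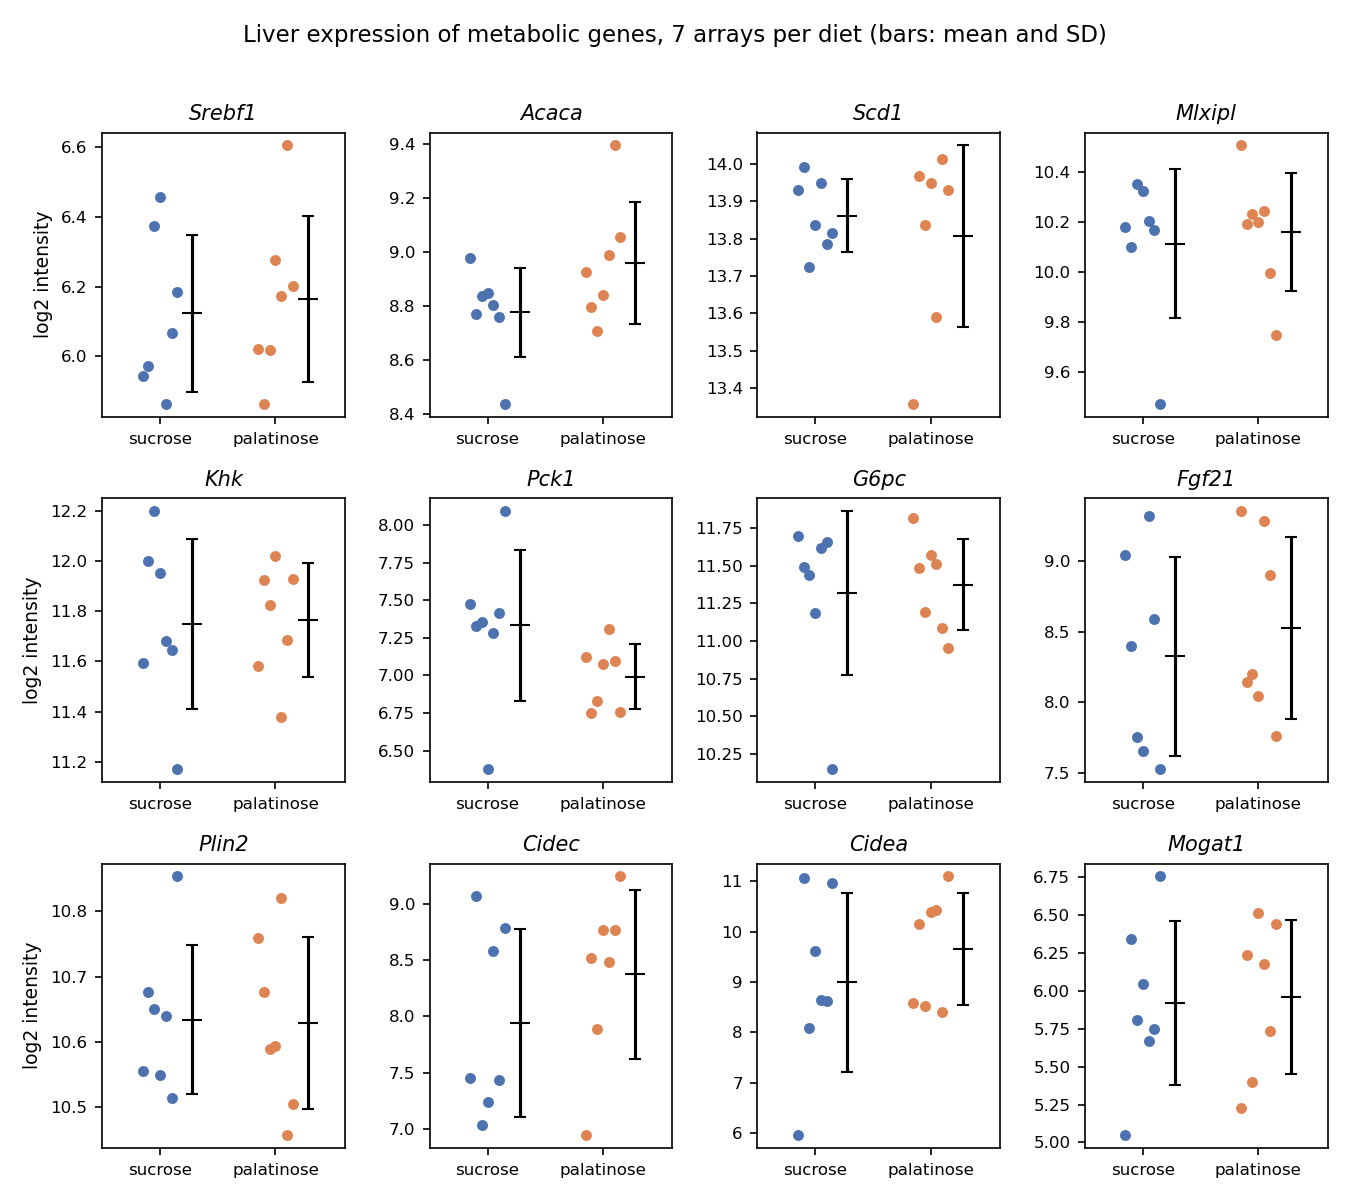
Log2 intensity of 12 metabolic genes in mouse liver, 1 point per array, 7 arrays per diet, with bars for the mean and SD. The ranges of the diets overlap for each gene; Cidea spans the widest range and Scd1 is the brightest.

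The list of metabolic hormone receptors, which also holds the protease gene Dpp4, was slightly lower with palatinose by some tests and not by others. Of 6 measured members 5 were lower, 0 passed over all genes or adjusted over the list alone, and the list fell by camera (adjusted p = 0.0323). The call is not kept with an estimated correlation, at an adjusted p = 0.264, nor by the exact permutation test (p = 0.00816, adjusted p = 0.269). Fry gave an adjusted p = 0.0186. The mean difference was -0.09 log2 (-0.15 to -0.03, with 10.08 ± 0.05 for sucrose and 9.99 ± 0.06 for palatinose, SD, n = 7). Without both arrays that carry the code 430, left out after the data were seen, the mean difference was -0.06. The exact permutation p was then 0.0341 before adjustment, and camera with an estimated correlation gave an adjusted p of 0.627. Klb, the co-receptor of FGF21, gave -0.26 (-0.49 to -0.03; -0.17 without SUC_424_02), Dpp4, for the protease that degrades incretins, -0.13, the adiponectin receptor Adipor2 -0.13 and the growth hormone receptor Ghr -0.17. The glucagon receptor Gcgr gave +0.24. Leaving out 1 array put the camera adjusted p above 0.05 for 7 of the arrays: PAL_417_02 (0.125), PAL_430_04 (0.0738), SUC_421_03 (0.0703), SUC_423_04 (0.0579), SUC_415_02 (0.0576), PAL_430_01 (0.0546) and SUC_417_01 (0.0508).

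Genes with male-biased expression in liver formed the other list that fell by camera. Of 15 measured members 13 were lower with palatinose, 0 passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.0284. With an estimated correlation the call is lost, at an adjusted p = 0.815; fry gave 0.820, and the exact permutation test p = 0.267. Per mouse the mean difference was -0.28 log2 (-0.77 to 0.22; 10.98 ± 0.23 with sucrose and 10.70 ± 0.56 with palatinose, SD, n = 7). The steroid dehydrogenase Hsd3b5 had 10.23 ± 1.01 with sucrose and 8.86 ± 2.43 with palatinose, a difference of -1.38 (-3.16 to 0.41). Cyp4a12b gave -0.48, the complement gene C6 -0.29 and Cyp2c70 -0.24. Without PAL_430_01 Cyp4a12b gave -0.29, and without PAL_417_02 C6 and Cyp2c70 each gave -0.16. The camera adjusted p was above 0.05 without PAL_417_02 (0.162), PAL_430_01 (0.113), PAL_430_04 (0.0738), SUC_421_03 (0.0703), SUC_423_04 (0.0579) or SUC_415_02 (0.0576). Without both arrays that carry the code 430 the mean difference was -0.06 (exact permutation p = 0.756). Female-biased genes had 4 higher and 2 lower of 6 measured (mean 0.03, -0.47 to 0.52, camera adjusted p = 0.928), and mean and median lay above 0 while the camera test pointed down.

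Interferon response genes did not pass. Of 15 members 12 were higher and 3 lower (mean 0.12, -0.06 to 0.30, camera adjusted p = 0.0622, and 0.815 with an estimated correlation). Isg15 gave +0.26, Irf7 +0.19, Oasl2 +0.23 (+0.12 without PAL_430_01) and Ifit3 +0.21 (+0.12 without SUC_423_04), whose other probes gave -0.18 and -0.09. The list passed by camera when 1 array was left out, without PAL_418_07 (0.00143), SUC_408_02 (0.0116), SUC_424_02 (0.0197) or PAL_407_04 (0.0313), and with array weights (0.0440); over all alternatives its adjusted p ran from 0.00143 to 0.881.

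Bile acid genes had 4 members higher and 11 lower of 15, and 0 passed (mean -0.10, -0.23 to 0.02, camera adjusted p = 0.134). The uptake transporter Slco1b2 gave -0.55 (-0.90 to -0.19), the sterol exporter Abcg5 -0.29, Baat, which conjugates bile acids, -0.23 (-0.06 without SUC_424_02), and their receptor Nr1h4 (FXR) -0.11 (-0.05 without PAL_430_01). The list passed without PAL_407_04 (0.0450) or SUC_408_02 (0.0499); with an estimated correlation and all arrays its adjusted p = 0.815. Of 18 cholesterol synthesis genes 13 were higher and 5 lower and 0 passed (mean 0.08, -0.31 to 0.47, camera adjusted p = 0.574). Srebf2, the transcription factor of this pathway, gave +0.34, Idi1 +0.29 (+0.18 without PAL_429_03), Hmgcs1 +0.27 (+0.16 without SUC_424_02) and Nsdhl -0.13 (other probes -0.21 to 0.01; -0.01 without PAL_430_01). Without PAL_430_01 the camera adjusted p of this list was 0.0456, and with array weights 0.0440; with an estimated correlation and all arrays its adjusted p = 0.941. PPAR alpha targets and fatty acid oxidation genes had 12 members higher and 13 lower, and 0 passed (mean -0.02, -0.18 to 0.14, camera adjusted p = 0.685). Ppara itself gave -0.28, Acot3 -0.60, Acaa2 -0.17 (other probes -0.19 to 0.13) and Crat +0.32, whose other probes lay between -0.31 and -0.22.

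In the insulin and IGF list 7 of 18 members were higher and 11 lower, and 0 passed (mean -0.06, -0.20 to 0.09, camera adjusted p = 0.369). Its member Socs2, a feedback inhibitor that growth hormone induces, had 8.32 ± 0.82 (SD, n = 7) with sucrose and 7.19 ± 0.72 with palatinose, a difference of -1.13 (-1.88 to -0.38, adjusted p = 0.604), and 6 of 7 palatinose arrays lay below the sucrose mean. Ptpn1, for a phosphatase of the insulin receptor, gave +0.31, Grb14 -0.23 (+0.12 on its other probe) and Pik3r1 -0.24. Without SUC_424_02 Ptpn1 gave +0.18 and Grb14 -0.14, and without PAL_430_01 Pik3r1 gave -0.16. Of 16 stress response genes 9 were higher and 7 lower, and the list did not pass (mean 0.05, -0.12 to 0.22, camera adjusted p = 0.574). Ddit3 passed adjusted over the list alone (0.0079) but not over all genes (adjusted p = 0.485), and its other probe gave +0.33. Adjustment over 1 list does not allow for the 33 lists. Of 454 list members, 2 passed in this way, Ddit3 and Slc40a1. The endoplasmic reticulum chaperone genes Hyou1, Pdia4 and Creld2 gave +0.31, +0.27 and +0.28; Pdia4 and Creld2 turned sign without the arrays that hold muscle or pancreatic transcripts.

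The iron handling list held 4 higher and 6 lower members of 10 and did not pass (camera adjusted p = 0.574, fry's test of change in either direction 0.205 after adjustment). Its mean difference was 0.02 (-0.13 to 0.18), with a median below 0 and a camera test that pointed down. Slc40a1, for the iron exporter ferroportin, had 11.28 ± 0.17 (SD, n = 7) with sucrose and 10.93 ± 0.16 with palatinose, a difference of -0.36 (-0.55 to -0.17, adjusted p = 0.575), and passed adjusted over the list alone (0.0091). Tfrc, the transferrin receptor that takes up iron, gave +0.34 (0.06 to 0.62) and +0.39 on its other probe, Hamp2, of the hepcidin family, +0.68 (-0.22 to 1.58; +0.45 without PAL_430_01) and Hjv, for hemojuvelin, -0.19 (-0.11 without SUC_417_01).

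Of the 33 lists tested, none other than the receptor and the male-biased list passed by camera, and the widest interval of a mean reached 0.513 log2 to either side. Ribosomal protein genes had 10 higher and 2 lower members of 12 (mean 0.08, 0.00 to 0.15, camera adjusted p = 0.104), and antioxidant NRF2 genes 11 higher and 4 lower of 15 (0.08, 0.00 to 0.15, camera adjusted p = 0.369). Camera adjusted p-values were 0.243 for the circadian (mean -0.12), cell cycle (0.18), immediate early (0.14) and endothelial (-0.07) lists and 0.257 for periportal markers (-0.11). They were 0.354 for amino acid catabolism, 0.534 for xenobiotic metabolism, 0.574 for pericentral markers, 0.699 for the acute phase and 0.778 for macrophage markers. They were 0.894 for lipoprotein assembly, for methionine and one-carbon metabolism and for hepatocyte markers, and 0.904 for the respiratory chain and for stellate cell and fibrosis genes. The median and the mean of the glycogen, gluconeogenesis, iron and stellate lists differed in sign. The other 8 lists had under 5 measured members, markers of cholangiocytes (Muc1, Krt23, Sox9), T and NK cells, B cells, neutrophils, erythroid cells, pancreatic acini, adipocytes and muscle. Their smallest adjusted p-values were 0.739, 0.877, 0.835, 0.722, 0.739, 0.764, 0.757 and 0.893 in that order.

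**Figure D2:**
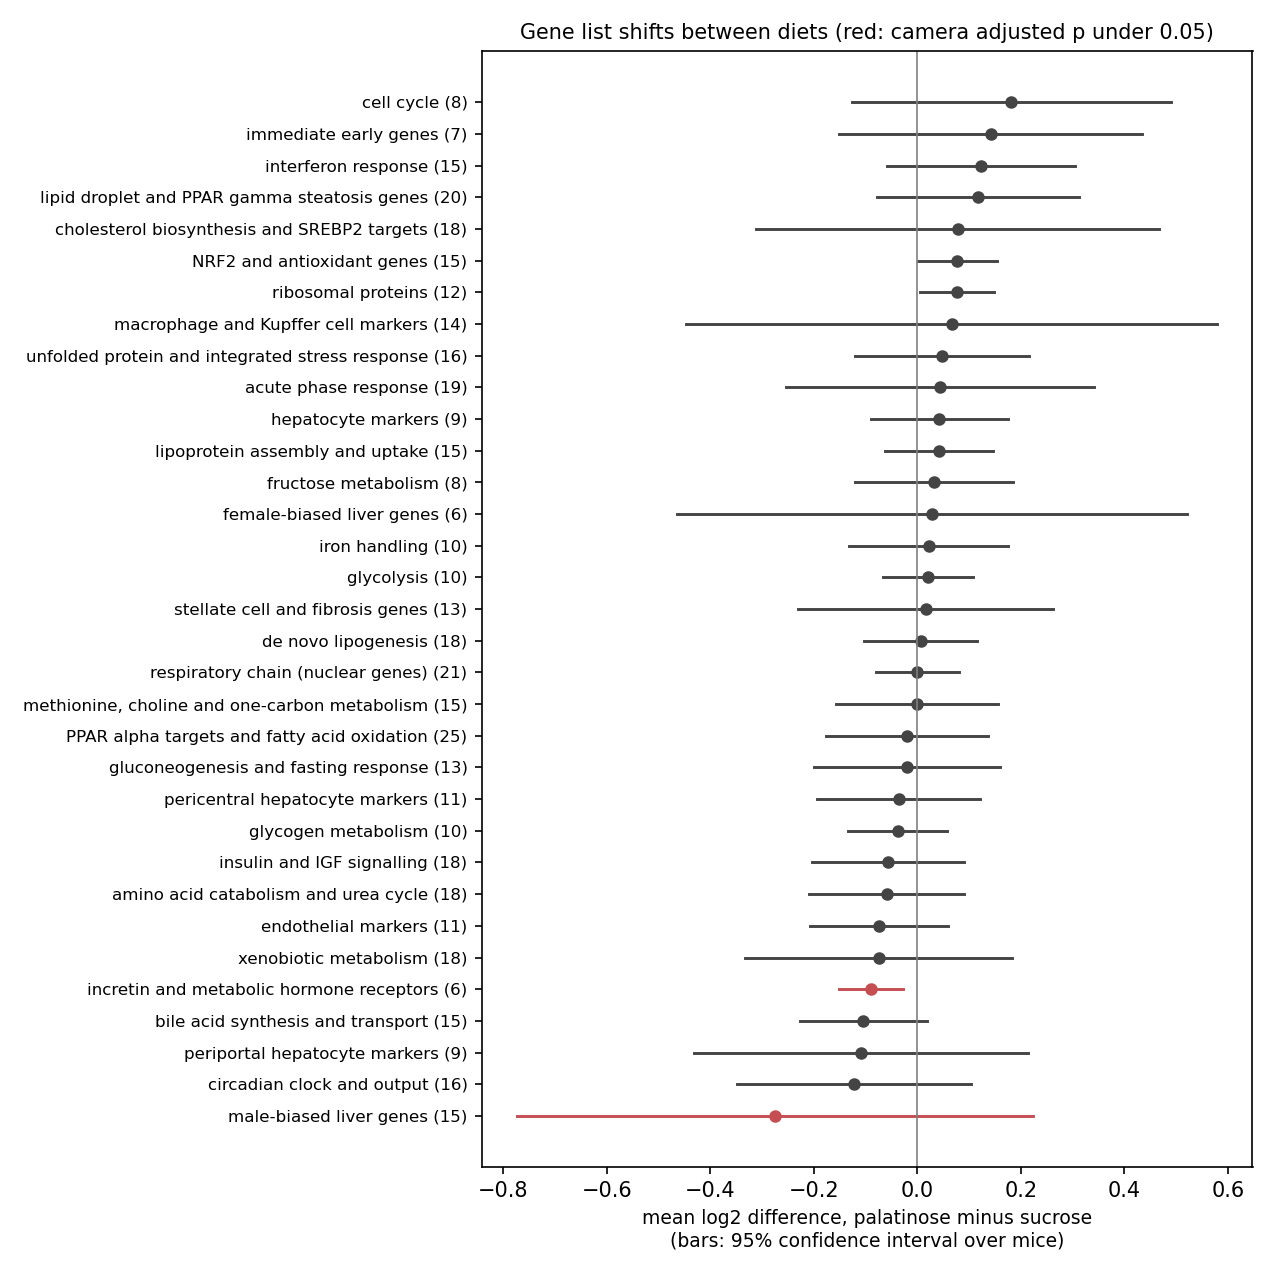
Mean log2 difference of palatinose minus sucrose for the 33 tested gene lists, with the number of measured members in brackets; bars are 95% confidence intervals over mice. The receptor list (-0.09) and the male-biased list (-0.28) are in red for a camera adjusted p under 0.05, and the interval of the male-biased list spans 0.

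Some liver samples held transcripts of skeletal muscle or pancreas. At least 5 of 9 muscle genes were detected on 4 arrays, sucrose SUC_415_02 and palatinose PAL_407_04, PAL_417_03 and PAL_429_03, and 0 on the other 10. On those 4 the background-subtracted signal of Acta1, skeletal muscle actin, was 234 to 1980, against -5 to 5 elsewhere. Not every muscle gene stood out on each: Mb was 9 on PAL_417_03, inside its 2 to 12 elsewhere. Of 12 pancreatic acinar genes SUC_415_02 had 12 and SUC_421_03 had 8 detected, and no other array over 3. Cela2a, a pancreatic elastase, reached 146 to 1136 on those arrays against -1 to 8 elsewhere. Ctrb1 was 164 on SUC_415_02 but 4 on SUC_421_03, inside its 3 to 11 elsewhere. Muscle transcripts were on 1 sucrose and 3 palatinose arrays (Fisher's exact test, two-sided p = 0.559). Without the 5 arrays with either tissue (5 sucrose and 4 palatinose left), 0 genes passed, the receptor list had an adjusted p of 0.0864 (0.0169 to 0.269 over its alternatives) and the cell cycle list passed at 0.0305 (0.815 with an estimated correlation and all arrays). The male-biased list passed by camera there too, at 6.81e-05 (0.815 with an estimated correlation and all arrays). The palatinose arrays left out had the 3 highest palatinose means of this list (11.25, 11.21 and 11.12). Leaving them out lowers its palatinose mean by construction, so this is no independent evidence of a fall. SUC_415_02 and SUC_421_03, also left out, had 11.11 and 11.22, above the sucrose mean of 10.98.

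**Figure D3:**
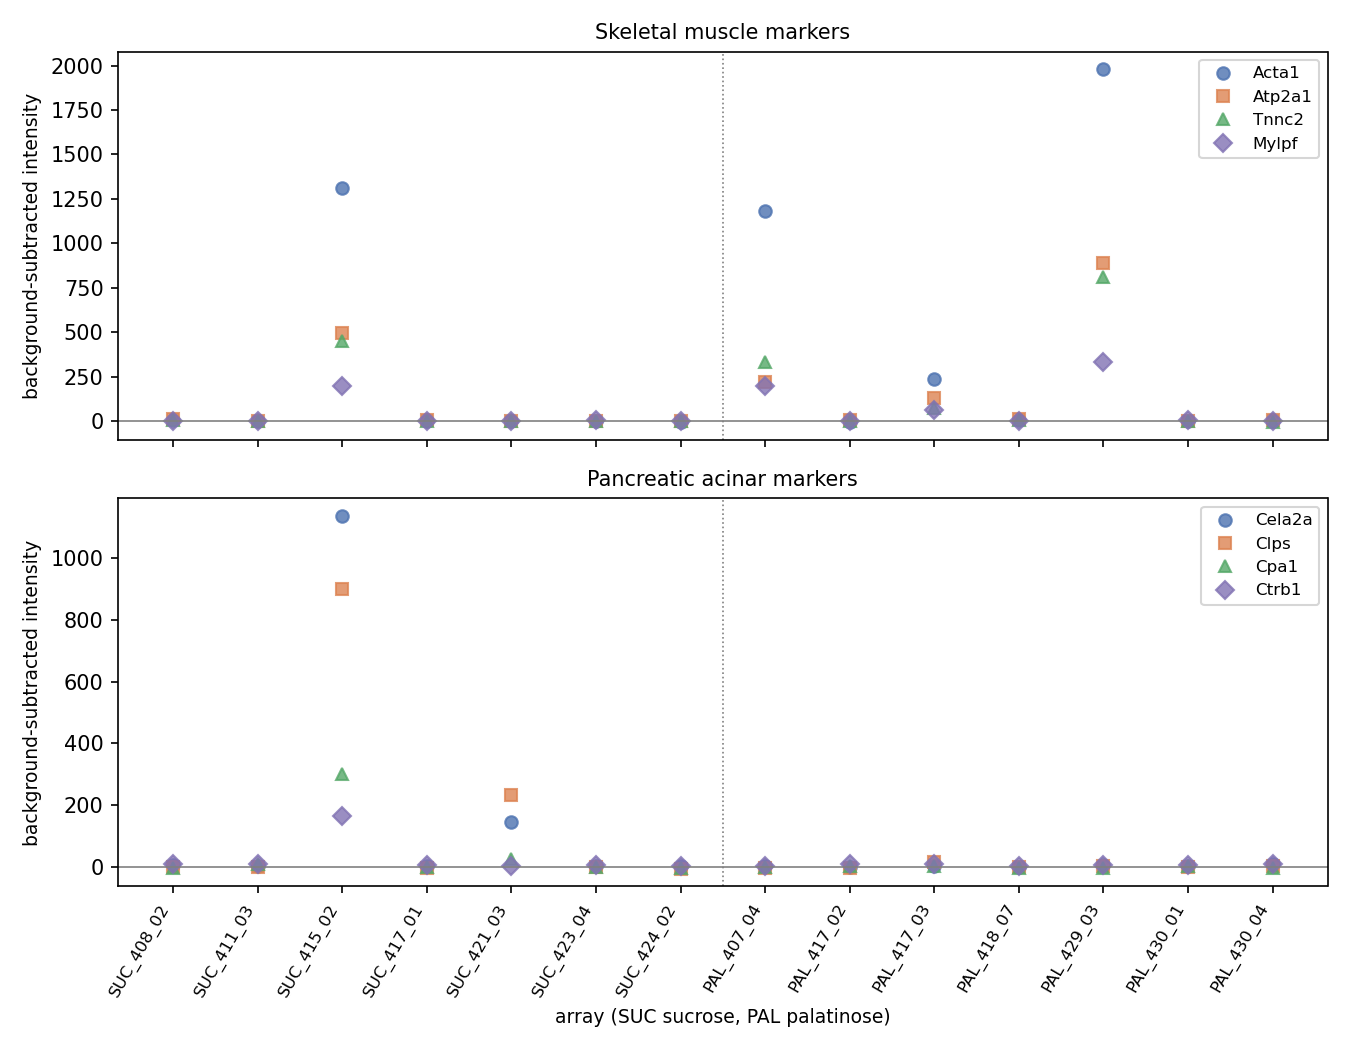
Background-subtracted intensity of 4 muscle and 4 pancreatic genes on each of the 14 arrays; sucrose arrays are left of the dotted line and palatinose arrays right of it. Muscle genes stand out on 4 arrays (Acta1 up to 1980) and pancreatic genes on SUC_415_02 and SUC_421_03 (Cela2a up to 1136), except Ctrb1, which is at 4 on SUC_421_03.

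Sucrose array SUC_424_02 stood apart from the other 13. Its array weight in limma was 0.196 against 0.626 to 1.74, and its mean signal of 257 was the highest of the 14. Probes of 1 gene diverged on it: their deviations differed with an SD of 0.414 log2, against 0.186 to 0.240 on the other arrays. Without it 0 genes passed, and the signs of Mlxipl, G6pc, Txnip, Khk and Plin2 turned.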

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

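The tests of the muscle and pancreatic transcripts, of sucrose array SUC_424_02 and of the male-biased genes were chosen only after the results were seen; the splits of the arrays were planned.

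Skeletal muscle transcripts stood out on 4 liver arrays and pancreatic ones on SUC_415_02 and SUC_421_03. The muscle genes came together: at least 5 of 9 were detected on each of the 4 arrays and 0 on the other 10, with Acta1 at 234 to 1980, Tnnc2 at 76 to 808 and Atp2a1 at 131 to 888. This is consistent with RNA from adjoining tissue in the liver piece, and whether it entered at dissection or in later handling was not tested. Of the 12 acinar genes, 2 or 3 were detected on each of the arrays without pancreatic transcripts too. Diet as a source cannot be told apart from chance, because 1 sucrose and 3 palatinose arrays with muscle transcripts are too few (Fisher's exact test, p = 0.559).

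Sucrose array SUC_424_02 lay apart from the other 13, with an array weight of 0.196 and 10 of the 20 single values that stood out. On it the probes of 1 gene diverged, with an SD of 0.414 against 0.186 to 0.240 elsewhere, and 2.62% of probe pairs differed over 2-fold against at most 0.146%. RNA or labelling quality is a candidate explanation for this divergence. Whether it accounts for the rest of the deviation stays open. The SD over genes on this array was also the highest (0.388 against 0.180 to 0.308). The probes of a gene correlated at 0.419, inside the range of the other arrays (0.354 to 0.660). Muscle or pancreatic tissue is argued against, since 2 of these markers were detected there, the number found on arrays without such tissue. No biological explanation was tested, because the design puts this mouse in no group of its own.

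Male-biased liver genes were lower with palatinose by camera (adjusted p = 0.0284, and 0.815 with an estimated correlation), and the lowest list means were those of PAL_430_01 (9.78), PAL_417_02 (10.19), sucrose array SUC_408_02 (10.55) and PAL_430_04 (10.56), against 10.98 ± 0.23 (SD, n = 7) over the sucrose arrays. A female mouse is argued against by Xist, detected on 0 arrays, and by Eif2s3y, detected on 14. Pairs of arrays that share a code in their column names had a higher mean correlation of their deviations from the diet mean (r 0.0843 against -0.0784 for other pairs, permutation p = 0.042, one-sided). This leaves the code open: r was 0.262 for the pair with code 430 and -0.0883 to 0.108 among SUC_417_01, PAL_417_02 and PAL_417_03. On average such deviations correlate below 0 within a diet by construction, and the permutation did not keep arrays to their diet. What the code stands for is not given in the sources used here. Lower growth hormone signalling cannot be told apart from chance with 14 arrays: Socs2 went with the list mean at Pearson's r of 0.312 (permutation p = 0.279, Spearman's rho 0.222, p = 0.446, r without the 2 farthest arrays 0.156). Diet stays open as well, at an exact permutation p of 0.267 for the list mean.

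Other splits of the 14 arrays into 7 and 7 do not let chance be excluded for the genes at an unadjusted p under 0.05 or for the lists. Of 100 splits, the real one included, 13 gave at least the 627 genes of the real split (highest other 1078), and 76 gave at least its 2 lists (highest other 11). With 0 genes at an adjusted p under 0.05 in the real split, 100 splits reach its count by construction (highest other 2), which says nothing about chance.

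Single values far from the other 6 of their diet stood out in 20 of 212 groups of values, where chance gives about 1 in 20. On SUC_424_02, log2 intensities were 7.03 for Adss, 7.03 for Zfp809, 11 for Baat, 8.21 for Grb14 and 7.78 for Klb, all above the other sucrose arrays. On the same array they were 8.44 for Acaca, 9.47 for Mlxipl, 10.1 for G6pc, 9.24 for Glyctk and 8.33 for Txnip, all below them. Of the other sucrose arrays, SUC_421_03 was low for Sec23a at 6.34 and for Acaa2 at 11.7. SUC_411_03 was high for Plin4 at 10.3, SUC_415_02 for Pik3r1 at 8.85 and SUC_408_02 for the mean of macrophage markers at 7.44. SUC_423_04 was high for Creld2 at 8.83 and low for Ifit3 at 7.99. Of the palatinose arrays, PAL_430_01 was high for Glyctk at 10.3 and low for Nr1h4 at 10.5, and PAL_418_07 was high for Lpin1 at 7.34.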

How the results depend on the processing

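The absence of gene calls held under each alternative except 2. Without the filter on dim probes 1 gene passed, Atg2a, and 1084 had an unadjusted p under 0.05. Atg2a passed there at the same difference of +0.30 log2, with a narrower interval (0.22 to 0.38 against 0.18 to 0.42). Its own values were unchanged, so the narrowing came from the variance that eBayes shares across features, which the added dim features changed. The call there is no separate evidence for this gene. The threshold of an unadjusted p under 0.05 gives 627 genes. Leaving out each array in turn gave 0 genes each time and 473 to 825 at an unadjusted p under 0.05. Of 73 named genes 58 turned sign under no alternative and 1 passed under any.

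The 2 list calls depended on the setting. The number of lists past the threshold was 1 with median scaling, 4 without a filter, 0 with detection p under 0.01 on all 14 arrays, 4 with array weights, 0 with an estimated correlation, 1 with fry and 0 with the exact permutation test. Leaving out 1 array gave 0 lists (5 arrays when left out: SUC_415_02, SUC_421_03, SUC_423_04, PAL_417_02 and PAL_430_04) to 7 (SUC_408_02). The receptor list had adjusted p-values of 0.110 with median scaling, 0.0718 with the stricter filter, 0.264 with an estimated correlation and 0.269 by exact permutation. Leaving out 1 array gave 0.0173 to 0.125. The male-biased list had 0.0740 with the stricter filter, 0.815 with an estimated correlation, 0.820 with fry and 0.881 by exact permutation, and leaving out 1 array gave 0.00158 to 0.162. The cause of these changes was not tested.

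Sets of arrays chosen after the data were seen changed calls too. Without both code 430 arrays the receptor list had 0.101 and the male-biased list 0.336, and without these and SUC_424_02 they had 0.134 and 0.420. Calls gained in these settings were cholesterol synthesis (1.22e-07 and 4.7e-07) and periportal markers (0.00375 and 0.0356); without both code 430 arrays their adjusted p-values with an estimated correlation were 0.627 and 0.721. Without the 5 arrays with muscle or pancreatic transcripts the receptor list had 0.0864, the male-biased list passed at 6.81e-05 and the cell cycle list at 0.0305; with an estimated correlation and all arrays both had 0.815. Those 5 arrays include the 3 palatinose arrays with the highest means of the male-biased list. Leaving them out lowers its palatinose mean by construction. Fewer samples remain in each case.

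No pairing by replicate number was seen. Arrays with the same number correlated at a mean of 0.0368 against -0.0043 for other pairs, and 2 of 14 correlated best with the array of their own number. A weak pairing cannot be excluded in this way, and the labels do not say that the numbers pair mice. A replicate block on the authors' values gave 0 genes, 617 at an unadjusted p under 0.05, 1 list, and 0.0623 for the receptor list. With the column code as a random block (consensus correlation 0.362), 0 genes passed and 618 had an unadjusted p under 0.05. A block for the slide was not run. Signal over background limits the dimmest probes. Cpt1a and Cd36 were detected on 0 arrays by their 1 probe each. Whether a low transcript or an unresponsive probe was the reason was not tested.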

Other observations

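All relations and single genes in this part were chosen only after values had been seen. Of 8 relations computed across the 14 livers, the firmest joined the lipid droplet gene Cidea with Mogat1, a monoacylglycerol acyltransferase: Pearson's r was 0.905 (permutation p = 2e-05, the smallest after adjustment at 0.00016) and Spearman's rho 0.837 (p = 0.00032). Without the 2 arrays farthest from the median of Cidea r was 0.872, and it was 0.956 within sucrose (exact p = 0.00238) and 0.910 within palatinose (exact p = 0.0129). Cidea and Cidec gave 0.668 (permutation p = 0.0086, adjusted 0.0229; rho 0.670, p = 0.0112; 0.632 without the 2 arrays), at 0.655 within sucrose and 0.656 within palatinose. Cidea gave 0.361 with Plin2 (permutation p = 0.207, adjusted 0.276; rho 0.301, p = 0.295; 0.523 without the 2 arrays) and 0.116 with Pparg (permutation p = 0.695, adjusted 0.695; rho 0.235, p = 0.417; 0.0455 without them). Within sucrose and palatinose Plin2 gave 0.607 (exact p = 0.154) and 0.0980 (exact p = 0.824), and Pparg -0.313 (exact p = 0.483) and 0.818 (exact p = 0.0236); the difference between diets was not tested. Cidea ranged from 5.97 to 11.1 log2 over the 14 livers.

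Livers with lower male-biased genes had higher macrophage markers. The list means gave r = -0.741 (permutation p = 0.00297, adjusted 0.0119; rho -0.670, p = 0.0105), -0.663 without PAL_430_01 and PAL_417_02, -0.969 within sucrose (exact p = 0.00238) and -0.718 within palatinose (exact p = 0.0692). Male-biased and female-biased genes gave r = -0.600 (permutation p = 0.0202, adjusted 0.0404) and rho = -0.741 (permutation p = 0.0031). Without the same 2 arrays r was -0.489 (permutation p = 0.106, n = 12), so the Pearson call was not kept. Within sucrose r was -0.00936 (exact p = 0.987) and within palatinose -0.833 (exact p = 0.0236). Male-biased and cholesterol synthesis genes gave 0.490 (permutation p = 0.0726, adjusted 0.116; rho 0.402, p = 0.156; 0.636 without the 2 arrays), at 0.673 within sucrose and 0.548 within palatinose.

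The palatinose arrays with code 430 shared values apart from the other 12 for several genes. Gpnmb, a marker of lipid-laden macrophages, was 6.92 and 7.52 on them and 4.42 to 5.76 elsewhere, and Ly6d was 8.01 and 8.07 against 5.04 to 6.93. Elovl3, a male-biased fatty acid elongase, was 6.64 and 6.66 against 7.11 to 8.80. The cholesterol synthesis gene Sqle was 6.95 and 6.99 against 7.48 to 8.84, and Cyp51 was 6.70 and 7.16 against 7.33 to 8.47. Among other male-biased genes looked at, Cyp7b1 was also apart. Hsd3b5, Susd4 and Cyp4a12b each had 1 of the 2 values inside the range of the other 12 arrays. The share of all features that sets these 2 arrays apart was not computed. With both left out, the cholesterol list was higher with palatinose at a camera adjusted p of 1.22e-07, which is 0.627 with an estimated correlation; over its alternatives this p ran from 1.22e-07 to 0.999. The mean difference was then 0.30 log2 (8.12 ± 0.13 with palatinose, n = 5, and 7.81 ± 0.25 with sucrose, n = 7, exact permutation p = 0.0467), against 0.08 with all arrays. Periportal markers were lower with palatinose at 0.00375 by camera, which is 0.721 with an estimated correlation (mean difference -0.25, exact permutation p = 0.109). The arrays left out were the lowest palatinose arrays for the cholesterol list and the highest for periportal markers. Leaving out such arrays of 1 diet moves its mean by construction, so this is no independent evidence of a difference.

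Some arrays held transcripts of other cells. On PAL_417_02 the plasma cell gene Mzb1 had a signal of 504, with 114 on PAL_418_07 and 6 to 23 on the other 12, the T cell gene Cd3d 67 and the B cell gene Cd79b 168, and 6 of 12 T and NK cell genes and 4 of 6 B cell genes were detected. Lor, a gene of keratinizing epithelium, was at 10.8 log2 on PAL_407_04, where Krt4 was at 7.12, while Sprr1a, another gene of such epithelium, was at 4.85, inside its range of 4.38 to 5.05 over all arrays. Cish, which growth hormone induces like Socs2, was 6.69 ± 0.77 (SD, n = 7) with sucrose and 6.07 ± 0.52 with palatinose, a difference of -0.62 (-1.26 to 0.02, adjusted p = 0.705).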
